A study of Mus musculus with 6 samples.

How the data were processed

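RNA sequencing values were deposited for 6 libraries from mice lacking Abcg8 in the whole body, 4 from liver and 2 from adrenal gland. Per the labels, all mice were male, received a low sterol diet with 0.005% ezetimibe (an inhibitor of intestinal sterol uptake) until weaning and then 1 of 4 diets for 12 weeks, with 1 mouse per group. Sterol doses of the diets were not given in the sources used here. Per the labels, RNA was extracted with Qiagen RNeasy and libraries were made with the TruSeq RNA Library Prep Kit v2, which does not mark the strand.

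The authors deposited a table of estimated counts per gene symbol and a table of TPM (a length-scaled share of transcripts) for the same libraries. The submitters' processing notes name Trimmomatic 0.33, HISAT2 2.0.5, kallisto 0.43.1 and the build mm10, without role or order. The annotation, the filters and the way transcripts were joined to genes were not given in the sources used here. The estimated counts the authors deposited were not whole for 39.1% to 49.3% of genes, and the deposited TPM values of each library summed to the total that this unit has by definition. The table held 33639 gene symbols, of which 32158 matched a gene name in GENCODE M21, the annotation used for coordinates on GRCm38 (mm10). It also held 1 row that names no gene, with 0% of the counts, which was left out. Scd1 in the ergosterol liver was listed at exactly 1330000. If that value was kept to 3 digits, its error is at most 0.376%, wider than its counting error. Reads of near-identical genes (the Mup, Cyp2a, Cyp2c, Cyp3a and Cyp4a families, Hspa1a with Hspa1b) and of overlapping or antisense genes cannot be told apart with certainty in such tables, so their values are uncertain.

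Estimated counts were rounded to whole numbers. Library totals ran from 41546678 to 50573529 estimated counts, so that a count of 0 allowed up to 0.0593 to 0.0722 CPM (counts scaled to the library total), taking 3 counts as the upper limit. Scaling used TMM factors from edgeR 4.0.16 (R 4.3.3), computed within each tissue: 0.83 for low sitosterol, 0.95 for high sitosterol, 0.93 for ergosterol and 1.35 for stigmasterol in liver, and 0.99 and 1.01 in adrenal. Values are called scaled CPM below. Genes were analysed at 1 CPM or more in at least 1 library of the tissue, which left 13378 genes in liver and 14224 in adrenal. Ratios between libraries were taken on the log2 scale with a prior count of 0.5, and each has an exact (Clopper-Pearson, conditional binomial) 95% interval. Intervals and limits cover counting error only, since reads copied by PCR are not independent molecules, and they say nothing about differences between mice.

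With 1 library per group there is no replicate check, no test across genes and no p-value. A gene was counted as higher or lower when its ratio was at least 2-fold (1 on the log2 scale) and its interval excluded equality. This compares 2 libraries, not 2 diets. The 39 gene lists (pathways and cell type markers), the named-gene rule, the comparisons and the alternatives, apart from the one said below to be added, were set in advance. For each list with at least 3 analysed members, the median log2 ratio was given with an order-statistic 95% interval and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. A list is said to stand apart below a percentile of 2.5 or the same distance from the top. Most lists did: 139 of the 225 list medians stood apart and 86 did not. For high sitosterol, ergosterol and stigmasterol against low sitosterol in liver, 12, 13 and 8 of 33 lists stayed within the random lists. In adrenal 12 of 27 did. Standing apart was thus common and does not by itself single out a list. The rule describes these libraries and is not a p-value. Members below the 1 CPM limit in every library of a tissue are not counted, as with 9 of the 18 female-biased genes, and since the limit is met by any 1 library it may favour members that differ. A scaling factor moves all genes alike, so it leaves a percentile as it is, apart from the effect of the prior count. The list of pancreatic acinar genes, in both tissues, and that of kidney tubule genes, in adrenal, had 2 analysed members each and were not used.

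Comparisons were high sitosterol, ergosterol and stigmasterol against low sitosterol in liver, high against low sitosterol in adrenal, and the 3 direct liver comparisons between sterols. Named genes were Abcg8 and Abcg5; 12 fixed genes per tissue; the 10 highest and 10 lowest ratios with an ordinary symbol, at least 10 CPM in the higher library and an interval excluding equality; and up to 4 members of each list with the largest ratios. Some genes that this rule names are not reported here. Other genes are said to be chosen after their values were seen. Overlaps of liver comparisons, which share 1 control, were set beside simulated unchanged libraries (Poisson counts, and counts with an assumed coefficient of variation of 0.2 between mice) and beside the overlap of independent lists.

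The procedure was tested on simulated data, with 67 genes altered 1.5-fold, 67 altered 3-fold and 66 altered 4-fold, up or down, in counts drawn from the real means and depths. For the high sitosterol liver comparison, with 13378 genes, 4-fold alterations were recovered in 100% of genes and 3-fold ones in 100% with counting error alone, and in 97.0% and 92.5% with a coefficient of variation of 0.2. Alterations of 1.5-fold, below the size rule, were counted in 4.48% and 8.96%. Among 13178 unaltered genes, 17 were counted with counting error alone and 364 with that assumed variation. For the adrenal comparison, with 14224 genes, the recoveries at 4-fold and 3-fold were 100% and 97.0%, or 98.5% and 94.0% with variation, and 3 or 274 of 14024 unaltered genes were counted. Intervals covered equality in 95.5% of unaltered liver genes and 94.9% of unaltered adrenal genes. The list rule was tested on log2 ratios drawn at random and independently for each gene, which lists of genes that vary together need not resemble. Of 60 random lists of 20 unaltered genes, 3 (5%) were called apart in liver and 5 (8.33%) in adrenal, and of 60 lists with a shift of 0.5 on the log2 scale, 91.7% and 80% were.

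Alternatives were DESeq2 1.42.0 size factors, total counts, no low-count filter, a prior count of 2, log2(TPM + 1), log2(TPM + 0.1), libraries thinned to the smallest, the mitochondrial and 20 most abundant genes left out, intervals widened for an assumed coefficient of variation of 0.2, and means in place of list medians. On both TPM scales genes were counted by the 2-fold limit alone, without an interval, so those counts differ from the main ones in rule as well as in scale. After seeing the data, subtraction of an estimated adrenal part from each liver library was added. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.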

Results

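Livers and adrenal glands of mice lacking Abcg8 were compared after 12 weeks on diets that differed in their sterols. Abcg8 and Abcg5 form the transporter that returns plant sterols to bile and to the gut lumen, and its loss causes sitosterolemia, in which plant sterols build up in blood and tissues. The question named for the series was how diets rich in sterols other than cholesterol affect gene expression. Sitosterol and stigmasterol are plant sterols, and stigmasterol differs from sitosterol by an extra double bond in the side chain. Ergosterol is the main sterol of fungi, with a methyl group in place of the ethyl group on the side chain and further double bonds. There were 4 liver libraries (low sitosterol, high sitosterol, ergosterol and stigmasterol) and 2 adrenal libraries (low and high sitosterol), with 1 mouse per group. Totals were 49125335, 48505203, 47789335 and 50573529 estimated counts in the livers, in that order, and 41546678 and 48058631 in the low and high sitosterol adrenals. The number of genes with counts was 18327, 18471, 18227 and 19330 in the livers and 20613 and 21199 in the adrenals. With 1 library per group no difference has a replicate check, so that each comparison is between libraries and not between diets.

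The targeted gene was examined first. Abcg8 had 51 counts in the low sitosterol liver (1.25 scaled CPM), 490 in the high sitosterol liver (10.6), 394 in the ergosterol liver (8.84) and 788 in the stigmasterol liver (11.6). Its partner Abcg5 stood at 11.7, 188, 72.8 and 132 scaled CPM in the same livers. In the adrenals Abcg8 had 2 and 3 counts and Abcg5 had 2 and 1. Abcg8 (GRCm38 chromosome 17, 84676302 to 84700333, plus strand) and Abcg5 (chromosome 17, 84658234 to 84683011, minus strand) share 6710 bases in GENCODE M21. The deleted part of Abcg8 was not given in the sources used here and the library kit does not mark the strand, so the total of the gene does not check the knockout, and Abcg8 and Abcg5 counts may include reads of each other.

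The sex given in the labels, male for every sample, was then compared with the Y-linked genes Eif2s3y and Ddx3y, chosen after their values were seen. Eif2s3y (chromosome Y, 1010543 to 1028847) had 1293, 1410, 1478 and 1680 counts in the low sitosterol, high sitosterol, ergosterol and stigmasterol livers, but 0 in the low sitosterol adrenal, which allows up to 0.0722 CPM, and 2 in the high sitosterol adrenal. Ddx3y had 1188 to 2201 counts in the livers and 3 in each adrenal. The X-linked copies Eif2s3x and Ddx3x had 10726 and 26263 counts in the low sitosterol adrenal and 13121 and 34204 in the high sitosterol adrenal. Another Y-linked gene, Kdm5d, still had 87 and 105 counts in the adrenals against 323 to 500 in the livers, and Uty had 9 and 19 against 252 to 443. Both have X-linked copies, and whether the adrenal counts are reads of those copies was not tested. The pair Eif2s3y and Ddx3y thus stood at 34.7% to 49.6% of the X-linked pair in the livers and at 0.0081% and 0.0106% in the adrenals. The male label was borne out by the livers and not by the adrenals, which are called the libraries labelled male in what follows.

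**Figure D1:**
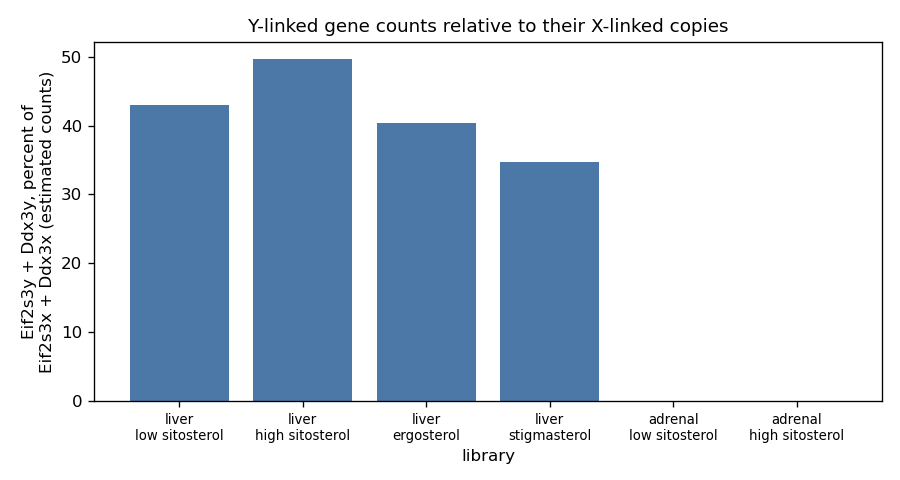
Summed counts of the Y-linked genes Eif2s3y and Ddx3y as a percent of those of their X-linked copies, with 1 bar per library. The Y-linked pair stands at 34.7% to 49.6% of the X-linked pair in the 4 livers and at 0.0081% and 0.0106% in the 2 adrenals.

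The high sitosterol liver was set against the low sitosterol liver. By the medians of their lists, genes of macrophages, of inflammatory signalling and of the cell cycle stood higher in the high sitosterol liver, and enzymes of cholesterol synthesis and genes more active in male than in female liver stood lower. Sult1e1, an estrogen sulfotransferase that is low in male liver, stood at 31.0 against 0.0489 scaled CPM, a ratio resting on 2 counts in the low sitosterol liver (log2 9.01, 95% interval 7.46 to 12.36). Gpnmb, a glycoprotein of lipid-loaded macrophages (chromosome 6, 49036546 to 49070929), was 189-fold higher. That ratio rests on 4 counts in the low sitosterol liver (log2 interval 6.36 to 9.60). In all, 1160 of 13378 genes were higher by the size rule and 575 were lower, so that 66.9% of the differences were higher.

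Cholesterol synthesis enzymes had 0 members higher and 9 of 20 lower, with a median log2 ratio of -0.80 (95% interval -1.17 to -0.39), and the list stood apart. Nsdhl (-1.67), Mvd (-1.55), Hsd17b7 (-1.39) and Cyp51 (-1.27) were the lowest, and Sqle, which makes squalene epoxide, was 2.01-fold lower. The sterol uptake and SREBP2 feedback genes, with 3 of 8 lower and a median of -0.35, stayed within the random lists. Targets of the liver X receptor (LXR), which senses oxysterols, had 6 of 15 members higher and 0 lower, with a median of 0.53. Abcg5 (16.0-fold higher), lipoprotein lipase Lpl (log2 3.34) and the targeted gene Abcg8 (3.07), which the list counts, led them. The cholesterol exporter Abcg1 was 3.04-fold higher, while the exporter Abca1 was at -0.22. Srebf1, the regulator of lipid synthesis that LXR activates, was at 0.87. Fatty acid and triglyceride synthesis genes had 0 higher and 7 of 18 lower (median -0.43), with Me1 at -2.19 and Acly at -1.68, although Fasn was at -0.25 and Scd1 at -0.08. Cyp7a1, the rate-limiting enzyme of bile acid synthesis (chromosome 4, 6265612 to 6275633), was 5.28-fold higher, and Cyp8b1, which makes cholic acid, was 2.16-fold lower. The bile acid synthesis list as a whole (median -0.28), the bile acid transport list (-0.08), the PPARA target list (-0.19) and the cholesterol esterification list (-0.05, with Soat2 at 0.10) stayed within the random lists.

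Inflammatory chemokines and cytokines had 10 of 14 members higher and 0 lower, with a median of 2.14 (0.50 to 2.74). Ccl4 (4.39), Ccl3 (2.74), Ccl5 (2.74) and Cxcl1 (2.56) stood out. Acute phase genes had 7 of 20 higher and 1 lower (median 0.69), with the iron-binding protein Lcn2 14.4-fold higher. Of the interferon-stimulated genes 5 of 19 were higher and 0 lower (0.73). Kupffer cell and macrophage markers had 14 of 18 higher and 2 lower (1.45, 1.20 to 1.61), among them Marco at 2.53 and Cd68 at 2.36, but the scavenger receptor Cd163 was at -3.06. Lipid-associated macrophage genes had 10 of 14 higher and 1 lower (2.69), led by Gpnmb (7.57) and Mmp12 (4.82), and share Lpl with the LXR list. B and plasma cell genes also stood apart (0.99), as did erythroid (0.38), stellate cell and matrix (3 of 21 higher and 1 lower, 0.38) and periportal hepatocyte genes (1 of 15 higher and 2 lower, 0.14). The neutrophil (0.34), T and NK cell (1.00), cholangiocyte (-0.02), endothelial (-0.20), adipocyte (-0.01) and hepatocyte identity lists (-0.12) stayed within the random lists, though the gluconeogenic enzyme G6pc was at -3.56. Cell proliferation genes had 13 of 21 higher and 0 lower, with a median of 1.62 (0.89 to 2.62) and Mki67 at 4.49. Of the male-biased liver genes 18 of 19 were lower (-2.48, -3.45 to -1.56), and 6 of 9 female-biased genes were higher (2.12), with Cyp2a4 at 7.39. The other 9 of the 18 female-biased genes listed were below 1 CPM in every liver. Mup15, a major urinary protein whose reads are hard to tell from those of its copies, had 97573 counts in the low and 0 in the high sitosterol liver. By counting error alone it was at least 36801-fold lower, a limit that does not cover reads assigned to its copies. Pericentral hepatocyte genes had 2 of 15 lower, Glul at -1.55 and Cyp1a2 at -1.37, and 1 higher, the transcription factor Tbx3 at 2.89, with a median of -0.67 that stood apart. Unfolded protein and integrated stress response genes had 7 of 16 lower and 1 higher (-0.76), Ddit3 at 1.43. Targets of CAR and PXR (4 of 21 higher and 2 lower, 0.36), of NRF2 (4 of 15 higher and 2 lower, 0.27) and of p53 (0 of 13 past the size rule, 0.39) stood apart on the higher side, and so did immediate early genes (4 of 14 higher and 1 lower, 0.54), while the clock list did not (0.18).

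Some of these differences came from a gene that stood out in a single library. The heat shock genes Hspa1a and Hspa1b stood at 449 and 793 scaled CPM in the high sitosterol liver and at no more than 9.04 and 74.6 in the other livers, and their reads are not told apart with certainty. The metallothioneins Mt1 and Mt2, chosen after their values were seen, were also high in the high sitosterol liver, at 914 and 510 against 122 and 70.4 in the low sitosterol liver, but not there alone, since the stigmasterol liver held 398 and 247. Moxd1 and Stox2 stood at 94.7 and 67.8 in the low sitosterol liver and below 1 in each other liver. Cyp11a1, Hsd3b1, Cyp11b1 and Star, which make adrenal steroids, were among the 10 lowest ratios, and the low sitosterol liver held adrenal cortex genes at a median of 0.127% of their adrenal level, against 0.0066% in the high sitosterol liver. Scaling by total counts moved the median of all genes by 0.19 and gave 1518 higher and 419 lower (78.4% higher). On the log2(TPM + 0.1) scale it moved by 0.26 and 81.5% of the differences were higher.

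The ergosterol liver was set against the low sitosterol liver. By the medians of their lists, genes of fatty acid oxidation and of bile acid synthesis stood higher in the ergosterol liver, and genes of the unfolded protein response stood lower. Cyp4a14, a fatty acid hydroxylase that is a target of PPARA, the fatty acid receptor of liver, was 71.7-fold higher (chromosome 4, 115486200 to 115496142), and Cyp7a1 was 10.8-fold higher (log2 3.44, 3.31 to 3.57). By the size rule 809 of 13378 genes were higher and 777 lower.

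PPARA target and fatty acid oxidation genes had 9 of 23 members higher and 0 lower, with a median of 0.83 (0.39 to 1.98). Cyp4a14 (6.16), Cyp4a10 (3.92), Acot1 (3.04) and Acaa1b (2.24) led the list, and the Cyp4a genes may share reads. Bile acid synthesis genes had 4 of 15 higher and 1 lower (0.53), with Cyp8b1 1.83-fold higher but Cyp7b1 at -1.49. Bile acid, sterol and phospholipid transport genes had 3 of 14 higher (0.56), with the exporter Abcc3 at 2.14. LXR targets had 5 of 15 higher and 0 lower (0.74, 0.18 to 1.13), with Abcg8 at 2.82, Abcg5 at 2.63 and Lpl at 2.35. Abca1 was at 0.13, Abcg1 at 0.74 and Srebf1 at 0.70. Cholesterol synthesis enzymes had 1 of 20 higher and 2 lower, with a median of -0.31 (-0.52 to 0.02) that stood apart but turned to 0.12 on the log2(TPM + 0.1) scale. Sqle was 2.92-fold lower and Mvd was at -1.48. The sterol uptake list (-0.24), the cholesterol esterification list (0.10, with Soat2 at 0.02) and the fatty acid synthesis list stayed within the random lists. In the last, with a median of 0.11, Gpam was at 2.02, Fasn at 0.20 and Thrsp at -2.33. Scd1, the desaturase that makes oleic acid (chromosome 19, 44394455 to 44407879), was 1.92-fold higher, from a count listed at exactly 1330000.

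Unfolded protein and integrated stress response genes had 0 of 16 higher and 8 lower (-1.02, -1.69 to -0.39), with Asns at -3.51 and Creld2 at -2.16. Chemokines and cytokines had 1 of 14 higher and 4 lower (-0.58, -1.79 to 0.44), with Cxcl2 at -2.47 and Ccl2 at -1.70. Neutrophil genes had 5 of 8 lower (-1.52), with S100a9 at -3.05 and S100a8 at -2.91. Acute phase (-0.27), interferon-stimulated (-0.01), T and NK cell (0.35), hepatocyte identity (-0.17), pericentral (0.14), periportal (0.11), stellate cell (-0.20), cholangiocyte (0.06), endothelial (0.15) and NRF2 target lists (0.13) stayed within the random lists. Kupffer cell markers had 3 of 18 higher (0.50), with Adgre1 at 1.69, and lipid-associated macrophage genes 5 of 14 higher and 1 lower (0.57). B and plasma cell (5 of 10 higher and 1 lower, 1.02), erythroid (0.46), CAR and PXR target (7 of 21 higher and 1 lower, 0.57) and p53 target lists (0.54) stood apart on the higher side, with Cdkn1a at 1.72. Proliferation genes had 8 of 21 higher and 2 lower (0.77). Immediate early genes had 7 of 14 higher and 1 lower (0.92), with Fos at 2.71. Adipocyte genes had 4 of 8 higher (0.99), with Cfd at 3.82 and Cidea at 3.03, but with no low-count filter the median was -0.27. Male-biased genes had 0 higher and 11 of 19 lower (-1.37), and female-biased genes 3 of 9 higher (0.64, or 0.93 with no low-count filter). Clock genes parted, with 4 of 17 higher and 5 lower (-0.71): Npas2, which works with Arntl, was at 3.36, and Dbp, of the opposite arm, was 20.4-fold lower. Myc and Gadd45g were 11.9-fold and 12.1-fold higher.

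Moxd1 and Stox2 and the adrenal genes Cyp11a1, Hsd3b1, Cyp11b1, Cyp21a1 and Star were again among the 10 lowest ratios, and the adrenal cortex genes stood at 0.0067% of their adrenal level in the ergosterol liver. Total counts moved the median of all genes by 0.16 and gave 1139 higher and 610 lower (65.1% higher), and the log2(TPM + 0.1) scale moved it by 0.34 and gave 1622 and 395 (80.4% higher), so that the even split rests on the scaling.

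The stigmasterol liver was set against the low sitosterol liver. It stood farthest from the low sitosterol liver by the number of genes, with 2903 of 13378 higher and 1042 lower (73.6% higher). By the medians of their lists, genes of dividing cells, bile duct cells, matrix-forming cells and lipid-associated macrophages stood higher in the stigmasterol liver. Enzymes of cholesterol and fatty acid synthesis, male-biased genes and pericentral hepatocyte genes stood lower. Cldn4, a tight junction protein of bile duct cells, was at 8.42, a ratio resting on 1 count in the low sitosterol liver (6.40 to 14.19). Gpnmb was 330-fold higher, resting on 4 counts there (log2 interval 7.14 to 10.37).

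Cholesterol synthesis enzymes had 1 of 20 members higher and 14 lower, with a median of -1.17 (-1.79 to -0.99). Mvd (-3.10), Tm7sf2 (-2.76), Fdps (-2.54) and Nsdhl (-2.49) were the lowest, and Sqle was 5.56-fold lower. Sterol uptake and feedback genes had 5 of 8 lower (-1.54), with Insig1 at -1.95. Fatty acid synthesis genes had 0 higher and 11 of 18 lower (-1.53, -2.01 to -0.57), with Thrsp at -5.05, Pnpla3 at -3.66 and Fasn 2.87-fold lower, while Scd1 was at -0.19, or 0.50 with total counts. LXR targets had 6 of 15 higher and 1 lower with a median of 0.12 that stood apart. It lay just above the random limit of 0.10, and the list counts the targeted gene Abcg8 (3.20), so the call may rest on that gene. Lpl was at 4.11, Abcg5 at 3.49 and Abcg1 4.54-fold higher, while Abca1 was at -0.02, or 0.67 with total counts, and Srebf1 at 0.12. Cyp7a1 was 2.78-fold higher and Cyp8b1 4.69-fold lower, and the bile acid synthesis list (-0.71), the bile acid transport list (-0.30) and the esterification list (-0.03, with Soat2 at -0.40, or 0.30 with total counts) stayed within the random lists. Slc10a1 and Slco1a1, which take up bile acids and organic anions, were at -3.76 and -6.36, and the basolateral exporter Abcc4 was at 3.14. PPARA targets had 8 of 23 higher and 1 lower, with Cyp4a14 at 4.74. Their median was 0.01, above nearly all random lists, and turned to -0.0412 with DESeq2 size factors.

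Proliferation genes had 17 of 21 higher and 0 lower (4.27, 1.95 to 5.25), with Ccnb1 at 7.05, Mki67 at 6.53 and Cdc20 at 6.52. Cholangiocyte genes had all 13 higher (3.65, 2.36 to 4.95, or 3.61 with a member at 0 counts set to its bound), with Cftr at 4.95 and Epcam at 4.17. Stellate cell, fibroblast and matrix genes had 18 of 21 higher (2.97, 1.80 to 3.87), with Timp1 at 4.85 and Col1a1 at 4.15. Lipid-associated macrophage genes had 11 of 14 higher and 1 lower (3.96), with Mmp12 at 6.37 and Itgax at 5.67. Kupffer cell and macrophage markers had 10 of 18 higher and 4 lower (1.26) and parted: Cx3cr1 and Ccr2, of monocyte-derived cells, were at 4.83 and 3.55, and Timd4 and Cd163, of resident Kupffer cells, at -3.80 and -5.07. B and plasma cell genes had 9 of 10 higher (2.67), with Igha at 5.39. Interferon-stimulated (9 of 19 higher, 0.70), p53 target (6 of 13 higher, 0.98, with Cdkn1a at 2.98), immediate early (0.77) and erythroid lists (0.68) stood apart on the higher side. The medians of acute phase genes (5 of 20 higher and 4 lower, 0.13), NRF2 targets (6 of 15 higher and 3 lower, 0.45), CAR and PXR targets (8 of 21 higher and 7 lower, 0.31, -1.62 to 2.15, with Cyp2b10 at 5.97 and Cyp2c37 at -5.10) and endothelial genes (1 of 15 higher and 1 lower, 0.43) also lay above those of the random lists, over members that went both ways. Gsta1, a glutathione transferase, was 463-fold higher. The chemokine list (7 of 14 higher and 1 lower, 1.12), the T and NK cell list (10 of 13 higher, 1.77), the neutrophil list (0.93) and the adipocyte list (3 of 8 higher and 2 lower, 0.10) stayed within the random lists. The random limits were themselves high and wide, at -0.12 to 1.41 for chemokines, 0.47 to 2.78 for T and NK cells and -0.04 to 2.67 for neutrophils. Staying within them therefore does not show that these genes were unchanged. Male-biased genes were lower in all 19 members (-5.03, -6.85 to -2.73), with Hsd3b5 408-fold lower. Mup15, at 0 counts, was at least 54174-fold lower by counting error alone, a limit that does not cover reads assigned to its copies. Female-biased genes had 7 of 9 higher (2.67, or 2.24 with no low-count filter). Pericentral genes had 9 of 15 lower (-1.66), with Cyp1a2 at -3.60 and Glul at -3.33, and the periportal list was at 0.13. Hepatocyte identity genes had 10 of 20 lower (-0.97, -1.17 to -0.46), a median within the random lists, with Apoa2 at -1.70. Unfolded protein and integrated stress response genes had 1 of 16 higher and 10 lower (-1.18), although Asns was at 2.41. Clock genes had 4 of 17 higher and 7 lower (-0.75), with Npas2 at 4.05 and Dbp at -3.95, a median that turned to 0.16 on the log2(TPM + 0.1) scale.

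The split between higher and lower genes rests on the scaling: total counts moved the median of all genes by 0.69 and gave 5285 higher and 401 lower (92.9% higher), and log2(TPM + 0.1) moved it by 0.86 and gave 6223 and 311 (95.2%). The 20 most abundant genes took 22.7% of the counts in the stigmasterol liver against 30.1% in the low sitosterol liver.

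**Figure D2:**
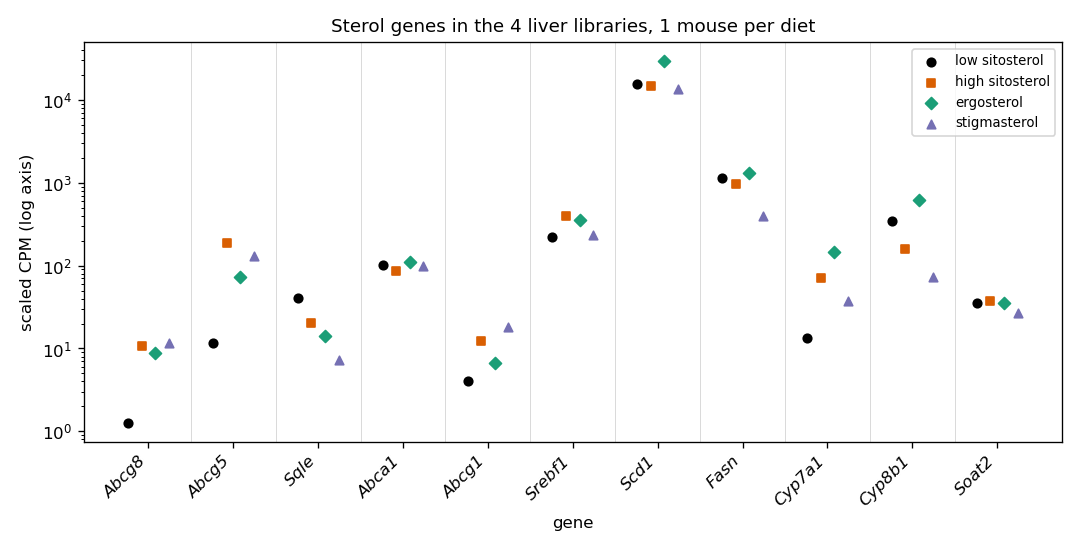
Scaled CPM, on a log axis, of sterol and lipid genes in the 4 liver libraries, with 1 point per gene and library. Cyp7a1 stands at 13.4 in the low sitosterol liver and at 70.7, 145 and 37.3 in the high sitosterol, ergosterol and stigmasterol livers.

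**Figure D3:**
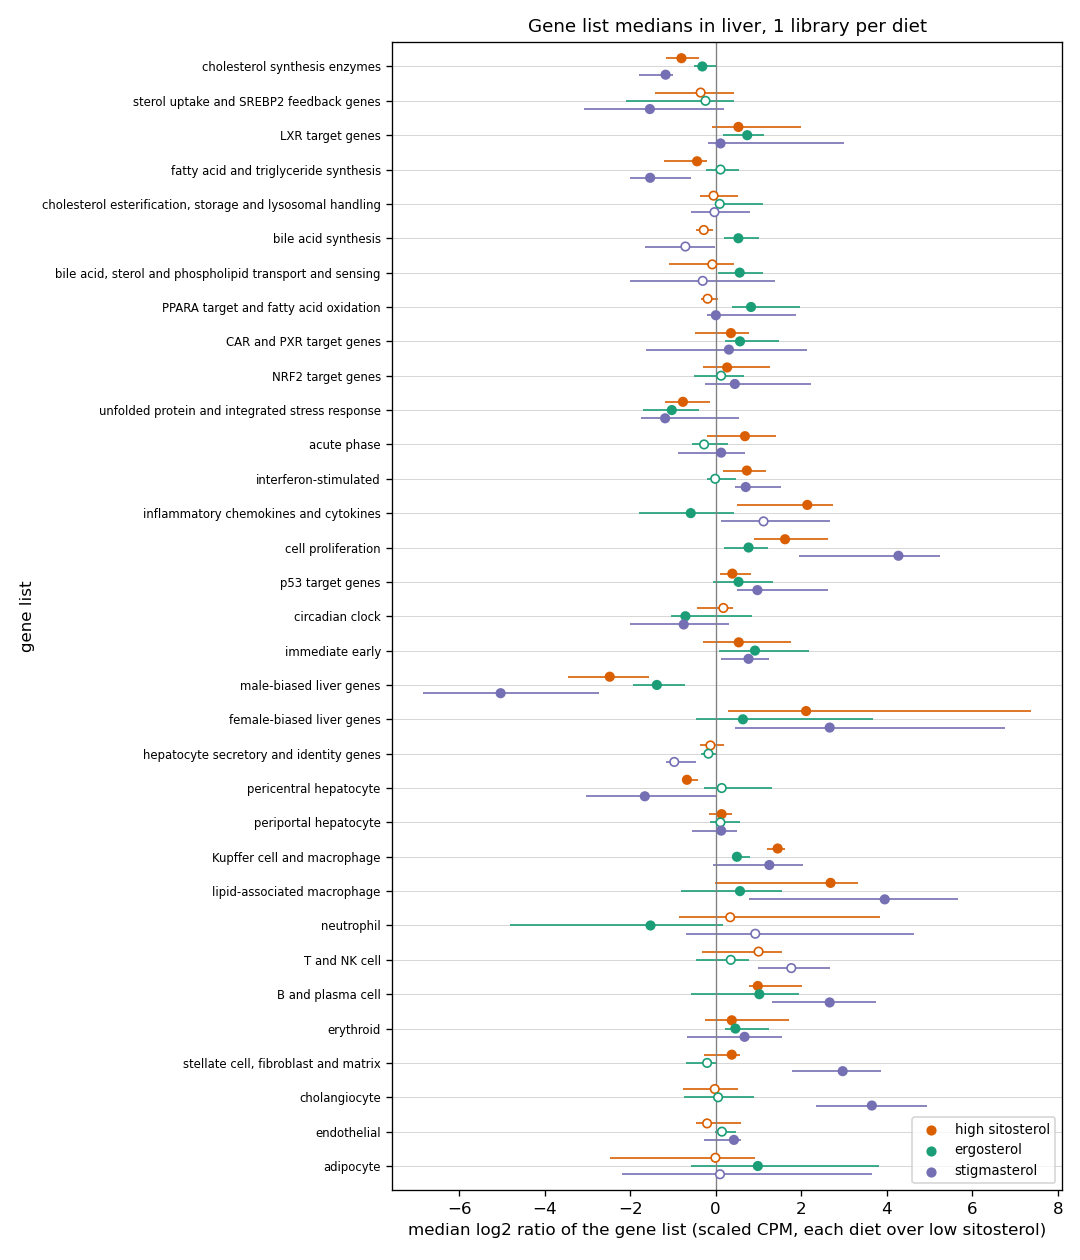
Median log2 ratio of each gene list in the 3 livers over the low sitosterol liver, with lines for the 95% interval of the median and filled points for lists that stand apart from 10000 matched random lists. Proliferation genes stand at 1.62, 0.77 and 4.27 for high sitosterol, ergosterol and stigmasterol.

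The sterols were also set against each other, with doses that were not given in the sources used here. In the stigmasterol liver 2204 genes were higher and 748 lower than in the high sitosterol liver (74.7% higher). The share was 91.8% with total counts, which move the median of all genes by 0.50. It was 93.8% with log2(TPM + 0.1), which moves that median by 0.60. These are differences between 2 libraries and cannot be assigned to the structure of the sterols. By the medians of their lists, genes of bile duct cells, matrix and dividing cells stood higher in the stigmasterol liver, and male-biased, pericentral and fatty acid synthesis genes stood lower. Cholangiocyte genes had 12 of 13 higher in the stigmasterol liver (4.02, 2.76 to 5.01), with Krt23 at 5.01 and Epcam 25.2-fold higher. Matrix genes had 16 of 21 higher (2.79), with Loxl1 at 4.32, and proliferation genes 15 of 21 higher and 1 lower (2.42). Male-biased genes had 16 of 19 lower (-1.99), pericentral genes 9 of 15 lower and 1 higher (-1.25) and fatty acid synthesis genes 7 of 18 lower (-0.82). Hepatocyte identity genes also stood apart on the lower side, with 8 of 20 lower and 1 higher (-0.80, -1.12 to -0.60). Cholesterol synthesis enzymes had 5 of 20 lower (-0.76, or 0.01 with log2(TPM + 0.1)), with Sqle 2.77-fold lower. PPARA targets had 6 of 23 higher (0.49). Chemokines had 3 of 14 lower (-0.41, but 0.0883 with total counts), with Cxcl1 at -2.43, and Kupffer cell markers 6 of 18 lower and 2 higher (-0.38, but 0.12 with total counts). The LXR list did not stand apart (0.03, -0.75 to 0.58), nor did the female-biased list (0.08, -0.62 to 0.75), and Abcg8 differed by 0.13 (-0.04 to 0.29). These intervals leave room for differences either way. Hspa1a was 191-fold lower in the stigmasterol liver, as it was high in the high sitosterol liver alone.

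Between the ergosterol and high sitosterol livers, genes of fatty acid oxidation, fatty acid synthesis and bile acid synthesis stood higher with ergosterol by the medians of their lists. Genes of chemokines, lipid-laden macrophages and dividing cells stood lower. In all, 827 genes were higher with ergosterol and 1198 lower (40.8% higher, or 52.4% with log2(TPM + 0.1), which moves the median of all genes by 0.09). PPARA targets had 11 of 23 higher with ergosterol (0.90, 0.67 to 1.77), bile acid synthesis genes 5 of 15 (0.81) and fatty acid synthesis genes 7 of 18 higher and 1 lower (0.73). Scd1 was 2.02-fold, Cyp7a1 2.05-fold and Cyp8b1 3.94-fold higher. Cholesterol synthesis enzymes had 3 of 20 higher (0.44). Chemokines had 12 of 14 lower (-2.53, -3.69 to -1.25), with Ccl2 at -4.20, and lipid-associated macrophage genes 9 of 14 lower (-1.86), with Gpnmb 63.6-fold lower. Proliferation genes had 10 of 21 lower (-0.98), and male-biased genes 12 of 19 higher and 2 lower (1.40). Neutrophil (6 of 8 lower, -2.78), interferon-stimulated (7 of 19 lower, -0.88) and acute phase genes (8 of 20 lower, -0.71) also stood apart on the lower side. So did Kupffer cell markers (8 of 18 lower and 2 higher, -0.84). The LXR list did not stand apart (-0.02, -0.86 to 0.35), although Abcg5 was 2.58-fold lower.

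Between the ergosterol and stigmasterol livers, enzymes of lipid and bile acid synthesis and pericentral hepatocyte genes stood higher with ergosterol by the medians of their lists. Genes of bile ducts, matrix and dividing cells stood lower. In all, 949 genes were higher with ergosterol and 2594 lower (26.8% higher, or 9.59% with total counts, which move the median of all genes by -0.53, and 9.84% with log2(TPM + 0.1), which moves it by -0.51). Cholangiocyte genes had 12 of 13 lower with ergosterol (-3.60, -4.90 to -2.21), matrix genes 19 of 21 lower (-2.68) and proliferation genes 19 of 21 lower (-3.23). Lipid-associated macrophage (12 of 14 lower and 1 higher, -3.55), chemokine (11 of 14 lower, -1.96) and neutrophil genes (7 of 8 lower, -2.97) also stood apart on the lower side. Fatty acid synthesis genes had 14 of 18 higher (95% interval of the median 1.12 to 2.27), with Fasn 3.30-fold higher, and cholesterol synthesis enzymes 12 of 20 higher (1.11, 0.93 to 1.25), with Tm7sf2 at 2.25. Hepatocyte identity genes had 4 of 20 higher and 0 lower, and 19 of 20 above 0, with a median of 0.78 (0.60 to 0.94) that stayed within the random lists. Male-biased genes had 16 of 19 higher (4.06) and pericentral genes 11 of 15 (1.98). Cyp8b1 (chromosome 9, 121914356 to 121916305) was 8.57-fold higher. The PPARA list did not stand apart (0.58, 0.18 to 1.10), nor did the clock list (0.23, -0.40 to 0.93) or the LXR list (0.15, -0.85 to 0.74).

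The 3 comparisons with low sitosterol shared genes. In all 3 diets 257 genes were higher and 148 lower. Simulated unchanged livers sharing the control gave 0.95 and 0.15 with counting error alone, and 19.9 and 4.80 with an assumed coefficient of variation of 0.2. Such simulated libraries pass few genes. With that variation 364 of 13178 unaltered genes were counted for high sitosterol, against 1160 higher and 575 lower in the data. The simulated overlaps are thus small in part by construction, and the excess over them is not a measure of shared response. High sitosterol and stigmasterol shared 933 higher and 288 lower genes, where independent lists would share 252 and 44.8, and 140 genes went opposite ways. High sitosterol and ergosterol shared 292 and 261 (70.1 and 33.4 for independent lists), with 87 opposite. Ergosterol and stigmasterol shared 500 and 279 (176 and 60.5), with 250 opposite. No overlap of independent lists was worked out for genes going opposite ways in these pairs, so whether the opposite genes are few or many cannot be told. Across genes, which are not independent replicates, the correlations of log2 ratios were 0.59, 0.43 and 0.37 in that order. Unchanged libraries gave 0.57, 0.52 and 0.57 with counting error alone, and 0.51, 0.50 and 0.51 with the assumed variation. The correlations of ergosterol with each other diet thus lay below those of unchanged libraries sharing a control. The simulated correlations come from the shared control alone, and differences particular to 1 library lower a correlation. The lower values therefore do not show that ergosterol shared less with the other diets than unchanged libraries would. The covariances were 0.80, 0.37 and 0.49, against at most 0.015 with counting error and 0.10 with the assumed variation. The control, a single library, could not be split, so how much of these overlaps comes from it cannot be told. At 405 genes the low sitosterol liver differed from each of the others in 1 direction (148 higher and 257 lower). By definition these are the genes shared by all 3 diets, seen from the control. That overlap therefore cannot tell a shared response from a trait of the control library. The other livers stood alone in this way at 224 genes for high sitosterol, 398 for ergosterol and 1917 for stigmasterol, of which 1560 were higher.

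The high sitosterol adrenal was set against the low sitosterol adrenal, both labelled male but with almost no Eif2s3y or Ddx3y RNA. By the medians of their lists, genes of neutrophils, macrophages and chemokines stood higher in the high sitosterol adrenal, and genes of fatty acid and cholesterol synthesis and of fat cells stood lower. Of 10 genes listed for the X zone, an inner layer of the mouse adrenal cortex, and for the inner cortex, 3 were lower by the size rule. The steroid synthesis genes as a group did not stand apart. Of 14224 genes, 545 were higher and 328 lower (62.4% higher). Adamts4, a protease of matrix proteoglycans, was 26.2-fold higher, and Pik3c2g, a gene of the X zone, 7.79-fold lower.

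Cortical steroid synthesis genes had 0 of 20 members higher and 0 lower (0.06, -0.22 to 0.28). Star, which brings cholesterol into mitochondria (chromosome 8, 25806555 to 25815982), was at 0.31, Cyp11a1, which cleaves the cholesterol side chain, at -0.64, Cyp11b1 at -0.01 and Cyp21a1 at -0.04. Scarb1, the receptor that takes up HDL cholesterol, was at 0.43 and Soat1, which esterifies cholesterol, at -0.44. The X-zone and inner cortex list, which shares Cyp11b1 with the steroid list, had a median of -0.52 (-2.11 to 0.25). In it, Pik3c2g was at -2.96 and Akr1c18 was 4.33-fold lower (chromosome 13, 4132615 to 4150654). Zona glomerulosa genes had 1 of 13 lower (-0.26), the angiotensin receptor Agtr1b at -1.22. Chromaffin cell genes had 0 of 17 higher or lower by the size rule, but their median of 0.51 (0.39 to 0.66) stood apart, with Phox2a at 0.91.

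Cholesterol synthesis enzymes had 1 of 20 lower and a median of -0.64 (-0.71 to -0.21), with Fdps at -1.02 and Sqle at -0.69. Sterol uptake genes had 1 of 7 lower (-0.58), Insig1 at -1.03. Fatty acid and triglyceride synthesis genes had 8 of 17 lower (-0.89, -1.48 to -0.49), with Pnpla3 at -1.77, Fasn at -1.67 and Scd1 at -1.55. Beside them, adipocyte markers had 9 of 14 lower (-1.22, -1.54 to -0.40), with the brown fat protein Ucp1 at -2.20. LXR targets (0.02, with Abca1 at -0.22, Abcg1 at 0.38 and Srebf1 at 0.27) and esterification genes (-0.10) stayed within the random lists.

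Neutrophil genes had 8 of 9 higher (1.89, 1.28 to 2.70), with Ngp at 5.17 and S100a8 at 2.13. Chemokines and cytokines had 8 of 14 higher (1.17, 0.58 to 2.75), with Il6 at 6.35 (4.39 to 12.21) and Ccl2 at 3.46. Macrophage markers had 9 of 17 higher (1.05), with Marco at 4.94, while lipid-associated macrophage genes, with 1 of 14 higher and 3 lower, stayed within the random lists (0.02) and Gpnmb was at -1.24. T and NK cell (0.91), B and plasma cell (5 of 8 higher and 1 lower, 1.26), erythroid (0.73) and endothelial lists (0.29) stood apart on the higher side. NRF2 targets had 4 of 13 higher (0.77), with the cystine transporter Slc7a11 at 2.21 and Srxn1 at 2.19. Ch25h, which makes the oxysterol 25-hydroxycholesterol, was 11.4-fold higher, and complement C3 4.26-fold lower. Unfolded protein and integrated stress response (-0.07), interferon-stimulated (0.10), proliferation (0.08), p53 target (-0.14) and clock genes (0.03) stayed within the random lists. So did immediate early (-0.16), hepatocyte (0.02) and matrix genes (0.13).

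**Figure D4:**
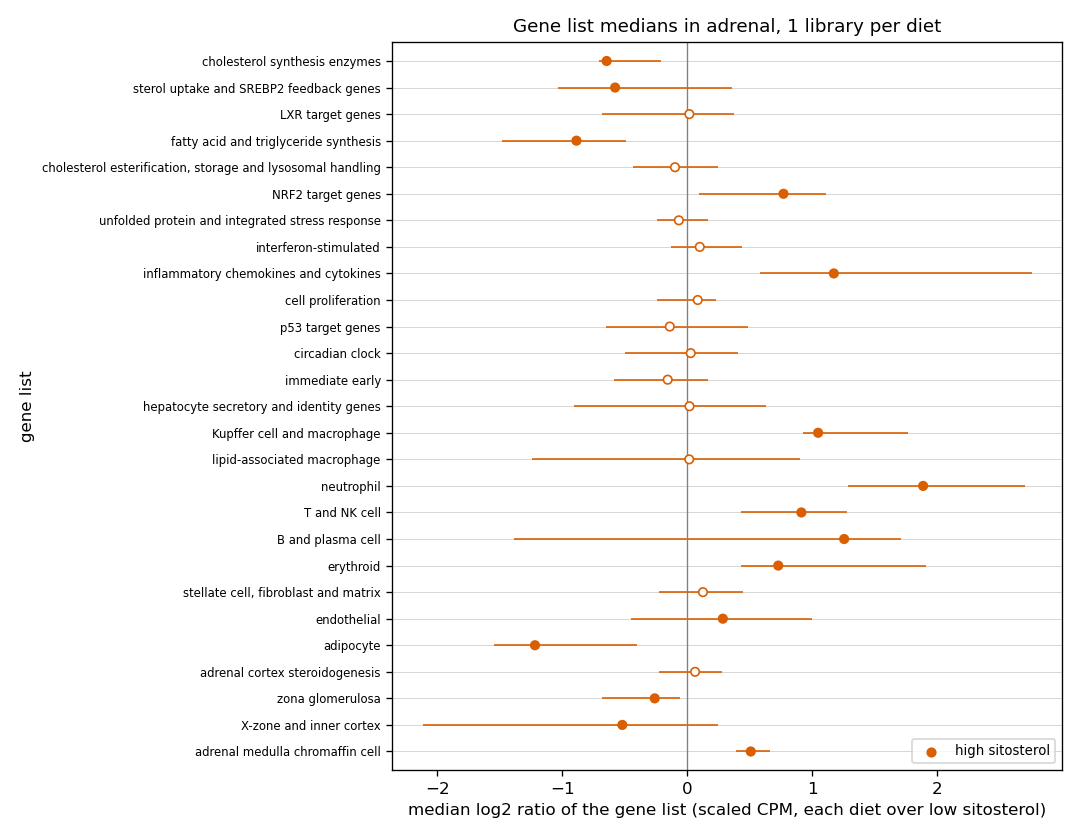
Median log2 ratio of each gene list in the high over the low sitosterol adrenal, 1 library each, with lines for the 95% interval of the median and filled points for lists that stand apart from 10000 matched random lists. Neutrophil genes stand at 1.89 and adipocyte genes at -1.22.

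High sitosterol in liver and in adrenal could be set side by side, though the Y-linked counts leave open whether both tissues came from the same mice or from mice of the same sex. Of 12477 genes analysed in both tissues, 126 were higher in both, where independent lists would share 28.0, and 38 were lower in both, against 7.12. Opposite ways went 19 genes higher in liver and lower in adrenal and 29 genes lower in liver and higher in adrenal, against 16.7 and 11.9. The correlation across genes was 0.15. The difference of log2 ratios, adrenal minus liver, had a median of -1.52 (-2.47 to -0.75) for proliferation genes, -0.54 (-0.86 to -0.12) for interferon-stimulated genes, -0.58 (-0.79 to -0.13) for p53 targets and 0.85 (0.02 to 1.71) for NRF2 targets. For cholesterol synthesis enzymes it was 0.30 (0.01 to 0.54), with both medians below 0, and for fatty acid synthesis genes -0.27 (-0.81 to -0.02). These intervals describe the spread over genes of a list, and the differences were not tested between mice.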

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

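The tests on Y-linked RNA and on clock genes and the subtraction of adrenal RNA were chosen only after the result was seen, while the other tests on the low sitosterol liver were fixed before their results.

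The low sitosterol liver drew attention because it held adrenal cortex genes at a median of 0.127% of their adrenal level, against 0.0066%, 0.0067% and 0.0169% in the high sitosterol, ergosterol and stigmasterol livers. Steroid genes switched on in that liver were weighed with 16 genes of the adrenal outside the steroid list. All were highest there, with a median ratio of 6.49 to the highest other liver. These genes were kept only if low in each other liver, with no such limit on this one. That filter went far to fix the outcome, so no conclusion is drawn from it. Adrenal RNA in the library may be the source: 10 chromaffin genes, which make no steroids, stood at 0.123% (95% interval 0.112 to 0.135) of their adrenal level and 10 cortical genes at 0.153% (0.148 to 0.157), a ratio of 0.80. The chromaffin genes, chosen under a looser limit of the same kind, stood at 0.0064%, 0.0018% and 0.0117% in the high sitosterol, ergosterol and stigmasterol livers. Steroid genes switched on would not by themselves account for that difference. Whether adrenal RNA entered at dissection, library preparation or sequencing stays open. After its subtraction 1184 genes were higher and 558 lower with high sitosterol, and 821 and 758 with ergosterol.

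The adrenals drew attention because Eif2s3y and Ddx3y had 0 and 3 counts in the low and 2 and 3 in the high sitosterol adrenal, against at least 1293 and 1188 in each liver, although all samples are labelled male. Adrenal glands from female mice are a candidate explanation: Akr1c18, an enzyme of the X zone that adult males have lost, stood at 117 scaled CPM in the lower adrenal and at 507 in the other. Depth is argued against, since Eif2s3x alone had 10726 and 13121 counts there. The 87 and 105 counts of Kdm5d, also Y-linked, go the other way unless they are reads of its X-linked copy, which was not tested. Loss of Y-linked expression in these glands alone was not tested and stays open, as does a gland from other mice than the livers.

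Clock genes stood apart in the ergosterol and stigmasterol livers. Another time of day at collection may account for it. Genes that peak with Arntl and those of the opposite arm moved apart by 2.88 with ergosterol and 3.32 with stigmasterol, against low sitosterol. Against high sitosterol they moved apart by 3.65 with ergosterol and 4.20 with stigmasterol. The separation was -0.94 for high against low sitosterol and -0.13 between ergosterol and stigmasterol. A shift of feeding time or an effect of the diet would part the arms alike and stays open. Collection times were not given in the sources used here. Other genes that vary over the day or with feeding could differ in these comparisons for the same reason, which was not tested.

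Lists that stood apart in opposite directions in different comparisons also drew attention, and these differences were not tested. Inflammatory chemokines and cytokines had medians of 2.14 in the high sitosterol liver, 1.17 in the high sitosterol adrenal and -0.58 in the ergosterol liver. Neutrophil genes had 1.89 in the high sitosterol adrenal and -1.52 in the ergosterol liver. Adipocyte genes had 0.99 in the ergosterol liver and -1.22 in the high sitosterol adrenal.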

How the results depend on the processing

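Of the alternatives given here, the subtraction of adrenal RNA was chosen after the result was seen, and the others before the data were examined. No paired analysis was possible because each group had 1 library. All 225 list medians stayed within their main interval with a prior count of 2, with thinned libraries and with abundant genes left out, but 27 moved out of it with total counts, 40 with log2(TPM + 1) and 41 with log2(TPM + 0.1), beside those that turned, given below. With means in place of medians 2 moved and 2 turned. Among the 86 lists that did not stand apart, medians turned sign in 3 with thinning, 7 without abundant genes, 4 with DESeq2 size factors, 6 with no filter, 13 with means, 21 with total counts, 31 with log2(TPM + 1) and 32 with log2(TPM + 0.1). The assumed coefficient of variation widens intervals only and cannot move a median. None of the 783 named ratios past the size rule turned its direction under the alternatives run, but their sizes moved: of all 1022 named ratios, 98 left their counting interval with DESeq2 size factors, 530 with total counts, 814 with log2(TPM + 1) and 674 with log2(TPM + 0.1), and 99 of 993 without abundant genes. Of the 239 named ratios below the size rule, 10 turned with total counts and 27 on each TPM scale, such as Scd1 with stigmasterol against low sitosterol, from -0.19 to 0.50 with total counts, and Soat2, from -0.40 to 0.30. Depth limits genes near the floor of 0.0593 to 0.0722 CPM. Except where the construction is named, the cause was not tested.

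With total counts, which shift all genes alike, stigmasterol against low sitosterol gave 5285 genes higher and 401 lower, stigmasterol against high sitosterol 3886 and 347, and ergosterol against stigmasterol 426 and 4018. The overlap of all 3 diets became 408 higher. With no low-count filter, where more genes are examined, the lower genes were 1126 for high sitosterol, 1313 for ergosterol and 1824 for stigmasterol against low sitosterol, and 1293 for stigmasterol against high sitosterol. The adrenal gave 1057 higher and 659 lower, ergosterol against stigmasterol 1459 higher, and the overlap of all 3 diets 328 lower. The low and high sitosterol livers stood alone at 632 and 374 genes.

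On the log2(TPM + 1) scale, which shrinks low genes, high sitosterol gave 560 higher and 154 lower in liver and 271 and 197 in adrenal. The lower genes were 188 for ergosterol and 234 for stigmasterol against low sitosterol, 192 for stigmasterol and 420 for ergosterol against high sitosterol, and 276 were higher for ergosterol against stigmasterol. On the log2(TPM + 0.1) scale the lower genes were 324, 395 and 311 for high sitosterol, ergosterol and stigmasterol against low sitosterol and 290 for stigmasterol against high sitosterol. Higher were 1622 for ergosterol and 6223 for stigmasterol against low sitosterol, 4376 for stigmasterol against high sitosterol and 417 for ergosterol against stigmasterol.

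Among lists that stood apart, the medians that turned were as follows, with log2(TPM + 1) before log2(TPM + 0.1). Cholesterol synthesis went from -0.31 to 0.11 and 0.12 for ergosterol against low sitosterol, and from -0.76 to 0.0043 and 0.0087 for stigmasterol against high sitosterol. The stigmasterol clock list went from -0.75 to 0.14 and 0.16. For stigmasterol against high sitosterol, total counts came to 0.074, 0.0883, 0.50 and 0.12 for the unfolded protein, chemokine, periportal and Kupffer cell lists, log2(TPM + 1) to 0.22, 0.18, 0.45 and 0.26, and log2(TPM + 0.1) to 0.23, 0.19, 0.45 and 0.26. The adipocyte list for ergosterol went from 0.99 to -0.27 with no filter. The stigmasterol PPARA list went from 0.01 to -0.0412 with DESeq2 size factors and to -0.0055 after the adrenal subtraction. Means in place of medians gave -0.0198 for the stigmasterol periportal list and 0.0133 for Kupffer cell genes in ergosterol against stigmasterol.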

Other observations

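The comparison of the 2 adrenal lists was chosen only after the result was seen. In the adrenal, a test of whether less fat tissue in the high sitosterol gland accounts for the lower fatty acid synthesis genes was also run. The median of the synthesis genes (-0.89) minus that of the adipocyte markers (-1.22) was 0.33, so that the synthesis genes lay no lower than the fat markers. It is given here as a value and was not weighed further.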
